A study of Homo sapiens with 8 samples.

How the data were processed

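RNA from CD4+ T cells and from the GM6990 lymphoblastoid line was labelled with biotin and hybridised to 8 single-colour arrays with 54675 probe sets each. Per the labels the CD4+ T cells came from normal individuals and were purified by negative selection, in which antibodies remove the other cell types. The deposited values are on the log2 scale and had been made by the authors with RMA, per the submitters' processing notes. RMA subtracts background, brings the arrays to a common distribution by quantile normalization and combines the probes of a probe set. Its version, software and settings are not given in the sources used here. The deposited log2 values ran from 1.93 to 14.4, and array medians from 4.52 to 4.58. Because quantile normalization equalises the arrays, a shift of most genes in a single direction is largely removed from these values. There are no detection calls, so low values near the floor understate folds, and the number of arrays limits the precision.

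Probe sets were named through the platform annotation, with symbols updated by gene identifier from the RefSeq gene table. A single gene symbol was given for 41097 probe sets, several for 1801, and 11777 were unnamed here. Of the probe sets with 1 symbol, 41043 matched a RefSeq gene identifier and 0 changed symbol. Probe sets with several symbols, the 62 control probe sets, XIST, TSIX and Y-linked genes were left out, which left 19740 genes. Of these, 10511 had more than 1 probe set, and the probe set with the highest mean stood for the gene. In 33 called genes other probe sets were called in the opposite direction; none of them is named in the text. Genes that this annotation does not name are not reported here.

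Arrays from the same source name were averaged with each other, giving 3 CD4+ T cell donors and 3 GM6990 samples. Each gene was tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, two-sided, with Benjamini-Hochberg adjustment over all genes, no covariates and no filter on dim genes. A gene was called at an adjusted p under 0.05 and a difference of at least 1 on the log2 scale, which is 2-fold. Every adjusted p of a gene in the text is from this limma fit, or from its repeat under the setting named beside it. Where a gene list is said to have members that rose or fell, those members were called, and a member that was not called may still have a small adjusted p. Tested on simulated data with the means and spreads of the 19740 genes and 200 changed genes, the fit called 85% of genes changed by 1.5 log2 and 99% of those changed by 3 log2, with 3 unchanged genes called. The simulated genes were independent, with the same spread in both groups and no shift by title form. These rates therefore check the fit and do not carry over to the real arrays.

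Before the data were examined, 37 gene lists with 702 memberships were fixed, of which 637 were measured. They cover T cell identity, T cell receptor signalling, T-lineage transcription factors, naive and resting T cells, T helper subsets, cell cycle restraint, B cell identity, B cell receptor signalling, B-lineage transcription factors, plasma cells, germinal centre B cells and immunoglobulins. They further cover MHC class II and class I presentation, NF-kB targets with genes induced by Epstein-Barr virus, cytokines and chemokines, DNA replication, mitosis, ribosome biogenesis, cytosolic ribosomal proteins, oxidative phosphorylation, glycolysis, cholesterol synthesis, nucleotide and one-carbon synthesis, and endoplasmic reticulum folding. The rest are interferon-stimulated, BCL2 family, DNA methylation and Polycomb, immediate early and housekeeping genes, genes induced after DNA damage, and markers of monocytes, platelets, cytotoxic cells, erythroid cells, dendritic cells and granulocytes. The set test was camera of limma with its preset correlation of 0.01 between genes, two-sided and adjusted over the 37 lists. It was repeated with the correlation estimated for each list, with ranks, and beside fry, which asks whether a list's genes move without comparing them with other genes.

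Named genes followed a rule also fixed in advance. It took the 8 largest differences in each direction among called genes whose groups did not overlap, up to 2 called members of each list with the largest difference in each direction (where none was called, the 2 with the largest difference of either sign), and a set of genes that check the labels. XIST, TSIX, Y-linked genes and genes whose level can show a genotype were never named. PSPH was placed among the latter after its values were seen, since the rule names such genes only as a class.

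The alternatives fixed in advance were other ways of treating repeat arrays, the title form as a block, the mean or the most variable probe set of a gene, calls per probe set, leaving out the dimmest 40% of genes, repeated quantile normalization, centring on array medians or ribosomal protein genes, eBayes with trend and robust settings, other thresholds, and leaving out each specimen. The planned choice of pseudocount did not apply, as the values were already on a log scale. Centring on either kind of spiked control and the use of title form 2 alone were added after seeing the data. Covariation of marker genes over donors was set against 10000 random lists of the same size and signal, and figures were drawn in Python 3.11.15.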

Results

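Messenger RNA levels were measured on 8 single-colour arrays, 4 of CD4+ T cells from 3 normal donors and 4 of GM6990, a lymphoblastoid line, that is, B cells immortalised by Epstein-Barr virus. The comparison asks which genes differ in expression between T cells taken from people and this B-lineage line. Lineage, immortalisation by the virus and growth as a line differ together between the groups, so no difference can be assigned to any of them alone. In each group 1 specimen was measured on 2 arrays, which were averaged, so n = 3 per group throughout. Nothing in the labels says that the 3 GM6990 samples were separate cultures, so the spread between these samples may be technical. Each p-value rests on a spread pooled over the donors and these samples. It can therefore understate the donor spread of genes that vary more between donors. The titles of GM6990 replicates 2 and 3 follow the pattern that marks repeat arrays of replicate 1, but their source names differ, so they were kept as separate samples. Array medians lay between 4.52 and 4.58 on the log2 scale, and the number of arrays limits the precision. The sample titles were grouped here into 2 forms. Replicate 1 of each group has plain titles (title form 1), and replicates 2 and 3 have titles with additions that differ between the groups (title form 2). No label links the groups by form, and the forms may mark batches. Medians by title form are given for form 1 and then form 2. All differences are GM6990 minus CD4+ T cells on the log2 scale.

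Among the genes set aside to check the labels, CD4, CD3E, MS4A1, CD79A and MKI67 differed in the direction of the labels, while CD14, PF4 and NKG7, markers of other blood cells, were also higher in the CD4+ T cell arrays. CD4, the co-receptor that defines helper T cells, read 9.70 ± 0.85 (SD, n = 3) in CD4+ T cells and 5.32 ± 0.15 (n = 3) in GM6990, a 20.7-fold lower level (adjusted p = 9.43e-05). CD3E, a chain of the T cell receptor complex, was 27.0-fold lower (adjusted p = 2.82e-04). In the other direction MS4A1, which encodes the B cell surface protein CD20, was 118-fold higher in GM6990 (4.83 ± 0.43 against 11.71 ± 0.21, n = 3 each, adjusted p = 1.71e-06), and CD79A, a signalling chain of the B cell receptor, was 34.0-fold higher. MKI67, a marker of dividing cells, was 10.5-fold higher in GM6990 (adjusted p = 7.4e-06). CD8A, the co-receptor of cytotoxic T cells, read 5.19 ± 0.57 and 4.56 ± 0.26 (n = 3 each), with an adjusted p of 0.141. CD14, a monocyte marker, was higher in the CD4+ T cell arrays (5.71 ± 0.41 against 3.80 ± 0.16), as were the platelet chemokine PF4 (6.28 ± 0.34 against 4.63 ± 0.19, a call lost with hybridisation control centring) and NKG7, a granule protein of cytotoxic cells (8.52 ± 1.42 against 4.67 ± 0.16, n = 3 each). With poly-A control centring CD4 (-2.57, adjusted p = 0.195), CD3E (-2.95, adjusted p = 0.13), NKG7 (-2.05, adjusted p = 0.205) and CD14 (-0.11, adjusted p = 0.933) lost their calls and PF4 turned direction (0.16). That centring adds the same upward amount to the difference of every gene. It also widened the median SD over genes from 0.174 to 1.40 in CD4+ T cells and from 0.156 to 1.48 in GM6990. Lost calls and smaller decreases under it, here and below, follow in part from this and are not particular to the genes named.

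**Figure D1:**
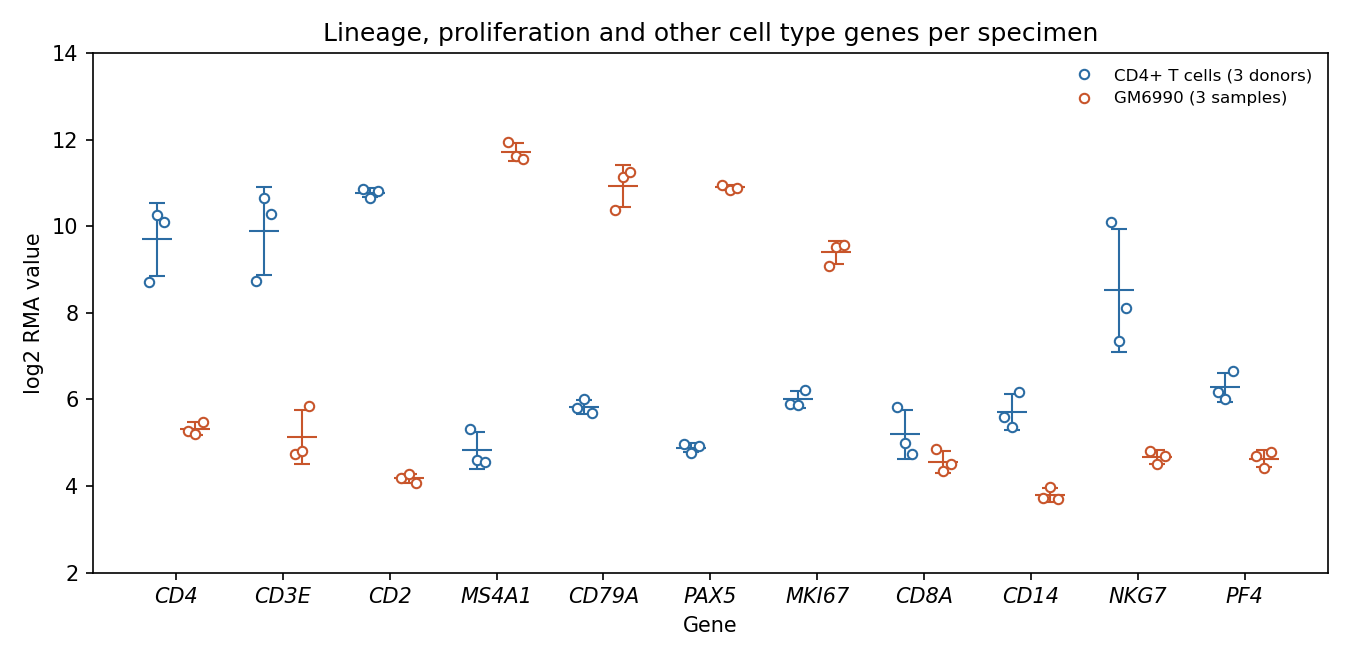
Log2 RMA values (vertical axis) of 11 genes (horizontal axis) in the 3 CD4+ T cell donors and the 3 GM6990 samples. Open circles are specimens, and the dash and whiskers are the mean and SD; CD4 averages 9.70 in the T cells and 5.32 in GM6990, and MS4A1 averages 4.83 and 11.71.

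Of 19740 genes tested, 2199 were higher and 1414 lower in GM6990 by at least 2-fold at an adjusted p under 0.05, together 18.3% of the genes. Among the largest increases were those of TNFRSF17, a receptor of plasma cells (7.41 ± 0.24 SE, adjusted p = 1.66e-06), BLNK, an adaptor of B cell receptor signalling (7.36 ± 0.13), DTNB-AS1, annotated as an antisense RNA (7.17 ± 0.14), and MS4A1 (6.88 ± 0.23). Others were the chemokine CXCL10 (6.41), the actin-bundling protein PLS3 (6.36), the pore-forming protein GSDME (6.10) and FCRLA, an Fc receptor-like protein of B cells (6.03). The largest decreases were those of LYZ, the lysozyme of myeloid cells (-8.53 ± 0.20 SE, adjusted p = 5.63e-07), RCAN3, a regulator of calcineurin (-7.37 ± 0.15), and the T cell adaptors FYB1 (-7.35) and TRAT1 (-7.12). The chromatin organiser SATB1 (-7.07), the transcription factor MAF (-6.88), the myeloid protein S100A8 (-6.78, and -7.49 without CD4 replicate 2) and the lectin-like receptor KLRB1 (-6.76) came next. Differences of at least 4 log2 numbered 97 upward and 117 downward. The 3 specimens of each group did not overlap in 3609 of the 3613 called genes, and in 44.4% of all genes tested, where chance gives 10%. Of the called genes named here, none overlapped.

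The split between higher and lower calls moved with the unit counted and with the scaling of the arrays. As deposited, 60.9% of the called genes were higher in GM6990 and the median difference of all genes was 0.08. Counted per probe set on the same scale, 3614 were higher and 3268 lower (52.5% higher) among the 41032 probe sets of the gene comparisons. The majority turned only when the probe sets outside these comparisons were counted as well, with 4047 higher and 4416 lower. Centring the arrays on ribosomal protein genes gave 2743 higher and 1153 lower (70.4% higher, median 0.26). Centring on the hybridisation controls, chosen after seeing the data, gave 5562 and 644 (89.6%, median 0.83), and centring on the poly-A controls, also chosen then, gave 852 and 36 (95.9%, median 1.88). Changes are given relative to the deposited scale.

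T cell genes were mostly lower in GM6990. In the T cell identity list 17 of 18 measured genes fell and none rose (17 adjusted over the list alone), with a median of -4.43 (by title form -4.0 and -4.78). CD2, an adhesion receptor of T cells, fell 96.6-fold, from 10.78 ± 0.11 to 4.18 ± 0.10 (SD, n = 3 each), and TRAT1 140-fold. Of the T cell receptor signalling genes 15 of 17 fell (15 adjusted over the list alone, median -3.13, by title form -3.24 and -3.07), led by FYB1 and by the kinase ZAP70 (-5.97 ± 0.29 SE, adjusted p = 6.35e-06). Of the T-lineage transcription factors 10 of 12 fell (10 adjusted over the list alone, median -3.95, by title form -4.48 and -3.68), among them SATB1 and MAF. Of the genes of naive and resting T cells 13 of 15 fell (13 adjusted over the list alone, median -2.95, by title form -3.10 and -3.25), with FOXP1, a factor that maintains quiescence, 82.6-fold lower. Each of these 4 lists passed the set test, with adjusted p = 8.87e-17, 1.44e-15, 2.16e-10 and 3.31e-12 in that order, and each kept its call with an estimated correlation (adjusted p between 0.0188 and 0.021). With poly-A centring 4, 4, 3 and 3 of their genes fell, with medians of -2.63, -1.32, -2.14 and -1.15.

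Genes that mark helper T cell subsets were lower in part. Of 18 measured, 8 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -1.13 that turned to 0.67 when arrays were centred on the poly-A controls. GATA3, the factor of type 2 helper cells, fell 17.6-fold (adjusted p = 2.96e-06) and STAT4, a transducer of interleukin 12 signals, 14.6-fold, both calls lost with poly-A centring (adjusted p = 0.205), under which 0 members fell. IKZF2, a factor of regulatory T cells, was the member that rose, 4.68-fold (7.70 ± 0.23 to 9.92 ± 0.35, SD, n = 3 each, adjusted p = 1.22e-04). The list passed the set test (adjusted p = 6.44e-05, and 0.0447 with an estimated correlation), and its median was -0.66 within title form 1 and -1.27 within title form 2. Some members that were not called read near the floor in both groups, where a fall could not show.

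Among 14 genes of the cell cycle restraint list, 9 fell and 1 rose (9 and 1 adjusted over the list alone), with a median of -1.64 (by title form -1.60 and -1.66) that became 0.17 when arrays were centred on the poly-A controls. The list also holds D-type cyclins, which promote the cell cycle, and the members that fell include such a cyclin. Its counts are therefore not of restraining genes alone. KLF2, which keeps T cells quiescent, fell 16.3-fold (12.26 ± 0.29 to 8.23 ± 0.69, SD, n = 3 each) and the antiproliferative protein TOB1 8.07-fold (adjusted p = 2.55e-05), calls lost with poly-A centring (adjusted p = 0.205 and 0.345), under which 0 members fell. CDKN1A, an inhibitor of cyclin-dependent kinases, went the other way and was 6.84-fold higher in GM6990 (adjusted p = 1.25e-04). The list passed the set test with an adjusted p of 4.72e-05, and the call was lost with an estimated correlation (adjusted p = 0.0585). Without CD4 replicate 1, as with the mean or the most variable probe set, 2 of its genes rose.

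B-lineage genes were mostly higher in GM6990. Of 19 B cell identity genes 15 rose and none fell (15 adjusted over the list alone), with a median of 2.29 (by title form 2.66 and 2.21). Of 15 genes of B cell receptor signalling 13 rose (13 adjusted over the list alone, median 3.41, by title form 3.29 and 3.34), and of 13 B-lineage transcription factors 10 rose (10 adjusted over the list alone, median 3.65, by title form 3.44 and 3.75). PAX5, the factor that commits cells to the B lineage, rose 64.6-fold, from 4.88 ± 0.11 to 10.90 ± 0.06 (SD, n = 3 each, adjusted p = 3.11e-07), and POU2AF1, a coactivator of octamer-binding factors, 45.4-fold. These 3 lists passed the set test (adjusted p = 7.13e-10, 5.45e-10 and 3.41e-08) and kept their calls with an estimated correlation (adjusted p = 0.021 for each).

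Plasma cell genes were mostly higher, and germinal centre genes split. Of 14 plasma cell genes 12 rose and none fell (12 adjusted over the list alone, median 3.33, by title form 2.32 and 3.69). ELL2, an elongation factor of antibody-secreting cells, rose 29.6-fold (adjusted p = 6.97e-06). The plasma cell list passed the set test with an adjusted p of 2.42e-07, and its call was lost with an estimated correlation (adjusted p = 0.0922). Of 11 germinal centre genes 5 rose and 2 fell (6 and 2 adjusted over the list alone), and the list missed the set test (adjusted p = 0.0976, median 1.07, by title form 1.31 and 0.95). The adaptor STAP1 (9.82-fold) and the cell cycle factor MYBL2 (8.08-fold) were higher in GM6990. BCL6, the repressor that defines germinal centre B cells, was 19.5-fold lower (8.06 ± 0.20 to 3.78 ± 0.63, SD, n = 3 each, adjusted p = 3.2e-05), and the transcription factor MYBL1 was 23.1-fold lower, both calls lost with poly-A centring (adjusted p = 0.205 and 0.167).

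Of 9 immunoglobulin genes only IGLC1, a lambda light chain constant region, was called (1 adjusted over the list alone). It read 9.30 ± 1.05 in CD4+ T cells and 14.29 ± 0.05 in GM6990 (SD, n = 3 each, adjusted p = 1.22e-04). Without CD4 replicate 1 the log2 difference was 5.59, and probe sets of this family can bind related lambda genes. Of the 9 probe sets of IGLC1, 2 were called higher and 0 lower. In GM6990 replicates 2 and 3 the IGLC1 value equalled the highest of the array (14.26 and 14.27), where differences can be compressed. The list missed the set test (adjusted p = 0.181, median 0.33, by title form 0.07 and 0.75), but passed it without CD4 replicate 1 (adjusted p = 0.0466, 2 genes higher), in title form 2 alone (adjusted p = 0.00723, 3 genes higher) and with either control centring (adjusted p = 0.0273). Without GM6990 replicate 1, or with the most variable probe set, 2 genes were higher.

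Of 14 genes of MHC class II presentation 10 rose in GM6990 and none fell (10 adjusted over the list alone, median 1.85, by title form 2.58 and 1.49), led by the lysosomal protease CTSH (17.0-fold, adjusted p = 9.64e-05) and HLA-DOB, a chain of the class II modulator HLA-DO (8.21-fold). The class II list passed the set test (adjusted p = 2.24e-05), and the call was lost with an estimated correlation (adjusted p = 0.205). Without GM6990 replicate 1, 1 class II gene fell. Of 15 class I genes 1 rose, 2 fell and 12 were not called (1 and 2 adjusted over the list alone), and the list did not pass (adjusted p = 0.572, median 0.16, by title form 0.24 and 0.20, mean 0.004, direction of the set test downward). Without CD4 replicate 2 the median was -0.04. The chaperone CANX was 2.23-fold higher, a call lost when its probe sets were averaged. With poly-A centring the CANX call was lost too, though its log2 difference grew from 1.16 to 2.96 (adjusted p = 0.13). Without GM6990 replicate 1, in title form 2 alone or with the title form as a block 2 class I genes were higher, and with the most variable probe sets 5 were lower. NLRC5, the transactivator of class I genes, was 4.55-fold lower in GM6990 (adjusted p = 1.8e-05), a call lost with poly-A centring (-0.38, adjusted p = 0.764). HLA-E was 2.21-fold lower, a call that was lost when arrays were centred on ribosomal protein genes or hybridisation controls, and whose direction turned under poly-A centring (0.66).

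Targets of NF-kB and genes that Epstein-Barr virus induces were mostly higher in the line. Of 27 measured, 17 rose and 2 fell (17 and 2 adjusted over the list alone), with a median of 1.76 (by title form 1.89 and 1.57). The chemokine CCL22 rose 56.4-fold, from 5.34 ± 0.44 to 11.16 ± 0.10 (SD, n = 3 each, adjusted p = 2.5e-06), and EBI3, a cytokine subunit named for its induction by the virus, 30.8-fold. GPR183, a chemotactic receptor that is also on resting T cells, was 4.64-fold lower in GM6990 (adjusted p = 0.00265), a call lost with poly-A centring (-0.41, adjusted p = 0.747). TNFAIP3, an inhibitor of NF-kB signalling, was 2.55-fold lower, a call lost with hybridisation control centring and turned in direction by poly-A centring (0.45). An adjusted p of 2.51e-07 came from the set test, and the call was lost with an estimated correlation (adjusted p = 0.0572). No uninfected B cells were measured, and a member that rose is also in the B cell identity list. The rise therefore cannot be assigned to the virus or to NF-kB.

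Genes of cell division were higher in GM6990 nearly without exception. All 36 measured mitosis genes rose (36 adjusted over the list alone), with a median of 3.61 (by title form 3.43 and 3.71). Each scaling tried moved the median of all genes upward, so none could test this direction. HMMR, which organises the spindle, rose 32.7-fold (4.17 ± 0.87 to 9.20 ± 0.13, SD, n = 3 each, adjusted p = 5.35e-05) and the cyclin CCNB1 28.8-fold. Of 32 DNA replication genes 30 rose (30 adjusted over the list alone, median 2.68, by title form 2.52 and 2.71), including RRM2, a subunit of ribonucleotide reductase (19.2-fold), and DTL, a regulator of replication origin licensing (17.1-fold). The set tests gave adjusted p = 7.81e-22 for mitosis and 1.9e-18 for replication, and both calls were lost with an estimated correlation (adjusted p = 0.0994 and 0.0715).

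Of 20 genes of nucleotide and one-carbon synthesis 15 rose (15 adjusted over the list alone, median 1.67, by title form 1.59 and 1.66), among them the thymidylate synthase TYMS (15.4-fold) and the serine pathway enzyme PSAT1 (9.63-fold, adjusted p = 1.35e-05). Of 18 genes of protein folding and secretion in the endoplasmic reticulum 13 rose (13 adjusted over the list alone, median 1.53, by title form 1.36 and 1.59), with the secreted folding factor MANF 5.05-fold and the disulphide isomerase PDIA6 4.30-fold higher. Of 17 cholesterol synthesis genes 11 rose (11 adjusted over the list alone, median 1.14, by title form 0.96 and 1.31), and SQLE, an early oxygen-dependent enzyme of the pathway, rose 11.0-fold (5.30 ± 0.41 to 8.76 ± 0.11, SD, n = 3 each) while MSMO1, which acts later, rose 5.78-fold. None of these 3 lists had a member that fell with all specimens, and without CD4 replicate 3 a gene of the endoplasmic reticulum list did (1 gene). With all probe sets of a gene averaged, 7 cholesterol synthesis genes rose. All 3 lists passed the set test (adjusted p = 8.88e-09, 7.2e-07 and 8.28e-05) and kept their calls with an estimated correlation (adjusted p = 0.021, 0.0212 and 0.0442). With poly-A centring 8, 5 and 4 of their genes rose.

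Of 28 genes of oxidative phosphorylation 16 rose and 12 were not called (16 adjusted over the list alone, median 1.04, by title form 0.82 and 1.10), with the ATP synthase subunits ATP5MC1 (4.31-fold, adjusted p = 1.24e-05) and ATP5MC3 (3.77-fold) in front. Of 19 glycolysis genes 14 rose and 1 fell (14 and 1 adjusted over the list alone, median 1.76, by title form 2.11 and 1.35). The hexokinase HK2 rose 6.64-fold and the phosphofructokinase PFKM 5.41-fold (adjusted p = 6.43e-06). The glucose transporter SLC2A3 was the member that fell, 15.9-fold (10.66 ± 0.48 to 6.67 ± 0.78, SD, n = 3 each), a call lost with poly-A centring (adjusted p = 0.205), under which 3 oxidative phosphorylation and 6 glycolysis genes rose. The set tests gave adjusted p = 4.34e-10 for oxidative phosphorylation and 1.99e-05 for glycolysis, and both calls were lost with an estimated correlation (adjusted p = 0.0757 and 0.211).

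Of 20 ribosome biogenesis genes 5 rose and 15 were not called (5 adjusted over the list alone, median 0.77, by title form 0.66 and 0.83), with the assembly factors NOP16 5.57-fold and MRTO4 4.38-fold higher. With the most variable probe sets 8 rose, and without GM6990 replicate 1 a gene fell (1 gene). None of 21 cytosolic ribosomal protein genes, whose median levels of 13.37 and 13.18 lay near the top of the range, where differences can be compressed, was called (0 adjusted over the list alone), and their median of -0.21 (by title form -0.13 and -0.23) turned to 0.55 with hybridisation control centring and to 1.60 with poly-A centring. RPL30 (-0.53 ± 0.10 SE, adjusted p = 0.00546) and RPL11 (-0.47 ± 0.16, adjusted p = 0.0546) differed most. Both lists passed the set test (adjusted p = 2.89e-04 upward and 0.00109 downward), and both calls were lost with an estimated correlation (adjusted p = 0.0637 and 0.0994), that of the ribosomal proteins also with control centring (adjusted p = 0.196). Of 12 housekeeping genes, often used as references, 3 rose (3 adjusted over the list alone, median 0.35, by title form 0.45 and 0.29), among them GAPDH (3.39-fold, adjusted p = 5.68e-05) and HPRT1 (2.40-fold). The HPRT1 call was lost when all its probe sets were averaged, a setting in which 1 housekeeping gene rose. With poly-A centring 0 were called, though the log2 differences grew. That of GAPDH went from 1.76 to 3.56 (adjusted p = 0.0545) and that of HPRT1 from 1.26 to 3.07 (adjusted p = 0.114). The housekeeping list missed the set test (adjusted p = 0.135).

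Interferon-stimulated genes were higher in part. Of 23 measured 11 rose and none fell (11 adjusted over the list alone), with IFIT3, an antiviral protein, 11.6-fold (5.92 ± 1.14 to 9.47 ± 0.40, SD, n = 3 each, adjusted p = 0.00138) and the interferon-induced IFI44L 9.10-fold higher (7.05 ± 1.53 to 10.23 ± 0.06). Without CD4 replicate 1 the log2 differences of 3.54 and 3.18 became 4.20 and 4.06. Without CD4 replicate 3, 1 gene fell. The list median of 0.92 was 0.37 within title form 1 and 1.43 within title form 2. The interferon list passed the set test (adjusted p = 0.00223), and the call was lost with an estimated correlation (adjusted p = 0.431).

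Of 21 immediate early genes, which respond within minutes to stimulation or handling of cells, 12 fell in GM6990, 7 were not called and 2 rose (13 and 2 adjusted over the list alone). FOS fell 59.0-fold (9.38 ± 1.36 to 3.50 ± 0.11, SD, n = 3 each, adjusted p = 1.87e-04) and the phosphatase DUSP1 45.2-fold, and without CD4 replicate 3 the log2 differences of -5.88 and -5.50 became -6.65 and -6.12. The transcription factor EGR3 (7.07-fold) and IER3 (3.02-fold) rose. The IER3 call was lost with poly-A centring, though its log2 difference grew from 1.59 to 3.4 (adjusted p = 0.0719). Under that centring 2 genes fell and the median was -0.05. The list median was -1.85 (by title form -1.62 and -1.96), and -1.14 without CD4 replicate 2. With an adjusted p of 2.81e-06 the list passed the set test, and the call was lost with an estimated correlation (adjusted p = 0.228).

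Most markers of monocytes and of cytotoxic cells were higher in the CD4+ T cell arrays, which held cells purified by negative selection. Of 16 monocyte markers 11 fell in GM6990 and none rose (12 adjusted over the list alone, median -2.06, by title form -1.76 and -2.08). LYZ read 11.52 ± 0.40 and S100A8 10.08 ± 1.30 in CD4+ T cells (SD, n = 3), and CD14, the monocyte surface marker, read 5.71 ± 0.41 there and 3.80 ± 0.16 in GM6990 (adjusted p = 3.34e-04). Of 15 markers of natural killer and cytotoxic cells 10 fell and none rose (10 adjusted over the list alone, median -2.84, by title form -3.84 and -2.23). The granzymes GZMA (77.9-fold, adjusted p = 3.18e-05) and GZMK (56.0-fold) led, and NKG7, a granule protein, read 8.52 ± 1.42 in CD4+ T cells and 4.67 ± 0.16 in GM6990 (n = 3 each; difference -3.85, and -3.06 without CD4 replicate 1 or -4.44 without CD4 replicate 2). Set tests gave adjusted p = 1.11e-09 for monocyte and 2.26e-06 for cytotoxic markers, and both calls were lost with an estimated correlation (adjusted p = 0.146 and 0.238). With poly-A centring 2 genes of each list fell (medians -0.26 and -1.03), and the calls of CD14 (-0.11, adjusted p = 0.933) and NKG7 (adjusted p = 0.205) were lost.

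Of 11 platelet markers 3 fell and 1 rose (3 and 1 adjusted over the list alone), with a median of -0.30 (by title form -0.17 and -0.39) that turned positive with hybridisation control (0.45) and with poly-A control centring. PPBP, a platelet chemokine, fell 18.6-fold (adjusted p = 1.19e-06), TUBB1, a platelet tubulin, 4.37-fold and the chemokine PF4 3.12-fold, the last turned in direction by poly-A centring (0.16), with which the calls of PPBP (adjusted p = 0.205) and TUBB1 (-0.32, adjusted p = 0.8) were lost as well. SPARC, a matrix protein also made by other cells, was the member that rose (3.52 ± 0.29 SE). The platelet list passed the set test (adjusted p = 0.0066), and the call was lost with an estimated correlation (adjusted p = 0.0896), with either control centring (adjusted p = 0.0504) and when the dimmest genes were left out (adjusted p = 0.343).

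The 3 remaining marker lists did not pass the set test. Of 9 dendritic cell markers 1 rose and 2 fell (1 and 2 adjusted over the list alone; adjusted p = 0.355; median 0.06, by title form 0.12 and -0.03, mean -0.53, direction of the set test downward). FCER1A, a chain of the high-affinity IgE receptor, was 24.3-fold lower in GM6990 (adjusted p = 2.54e-04; log2 difference -4.60, and -5.20 without CD4 replicate 1) and the lectin CLEC10A 2.45-fold lower, a call lost with hybridisation control centring (adjusted p = 0.259) and turned in direction by poly-A centring (0.51). The lectin CLEC4C was 2.37-fold higher, a call lost without GM6990 replicate 2 (0.95) or GM6990 replicate 3 (adjusted p = 0.0501). With poly-A centring the CLEC4C call was lost though its log2 difference grew from 1.25 to 3.05 (adjusted p = 0.115). That of FCER1A was lost with a difference that shrank to -2.80 (adjusted p = 0.154). Of 7 erythroid markers the globin HBB fell (1 adjusted over the list alone; -1.84 ± 0.46 SE, adjusted p = 0.0186), a call lost without GM6990 replicate 1 (adjusted p = 0.0555) or GM6990 replicate 3 (adjusted p = 0.0654), and with poly-A centring (-0.04, adjusted p = 0.979). The erythroid list had a median of 0.12 (by title form 0.10 and 0.03), a mean of -0.18 and a set test directed downward with adjusted p = 0.835. Of 11 granulocyte markers the mast cell protease CPA3 fell (1 adjusted over the list alone; -1.29 ± 0.31 SE, adjusted p = 0.0147). That call was lost without GM6990 replicate 2 (adjusted p = 0.0655) or CD4 replicate 3 (-0.93) and with hybridisation control centring (adjusted p = 0.26), and poly-A centring turned its direction (0.51). The granulocyte list, with a median of -0.29 (by title form -0.16 and -0.19) that turned to 0.47 and 1.52 under hybridisation and poly-A control centring, missed the set test (adjusted p = 0.0684), but passed it without CD4 replicate 2 (adjusted p = 0.0175, 3 genes lower) and with ranks (adjusted p = 0.0351).

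**Figure D2:**
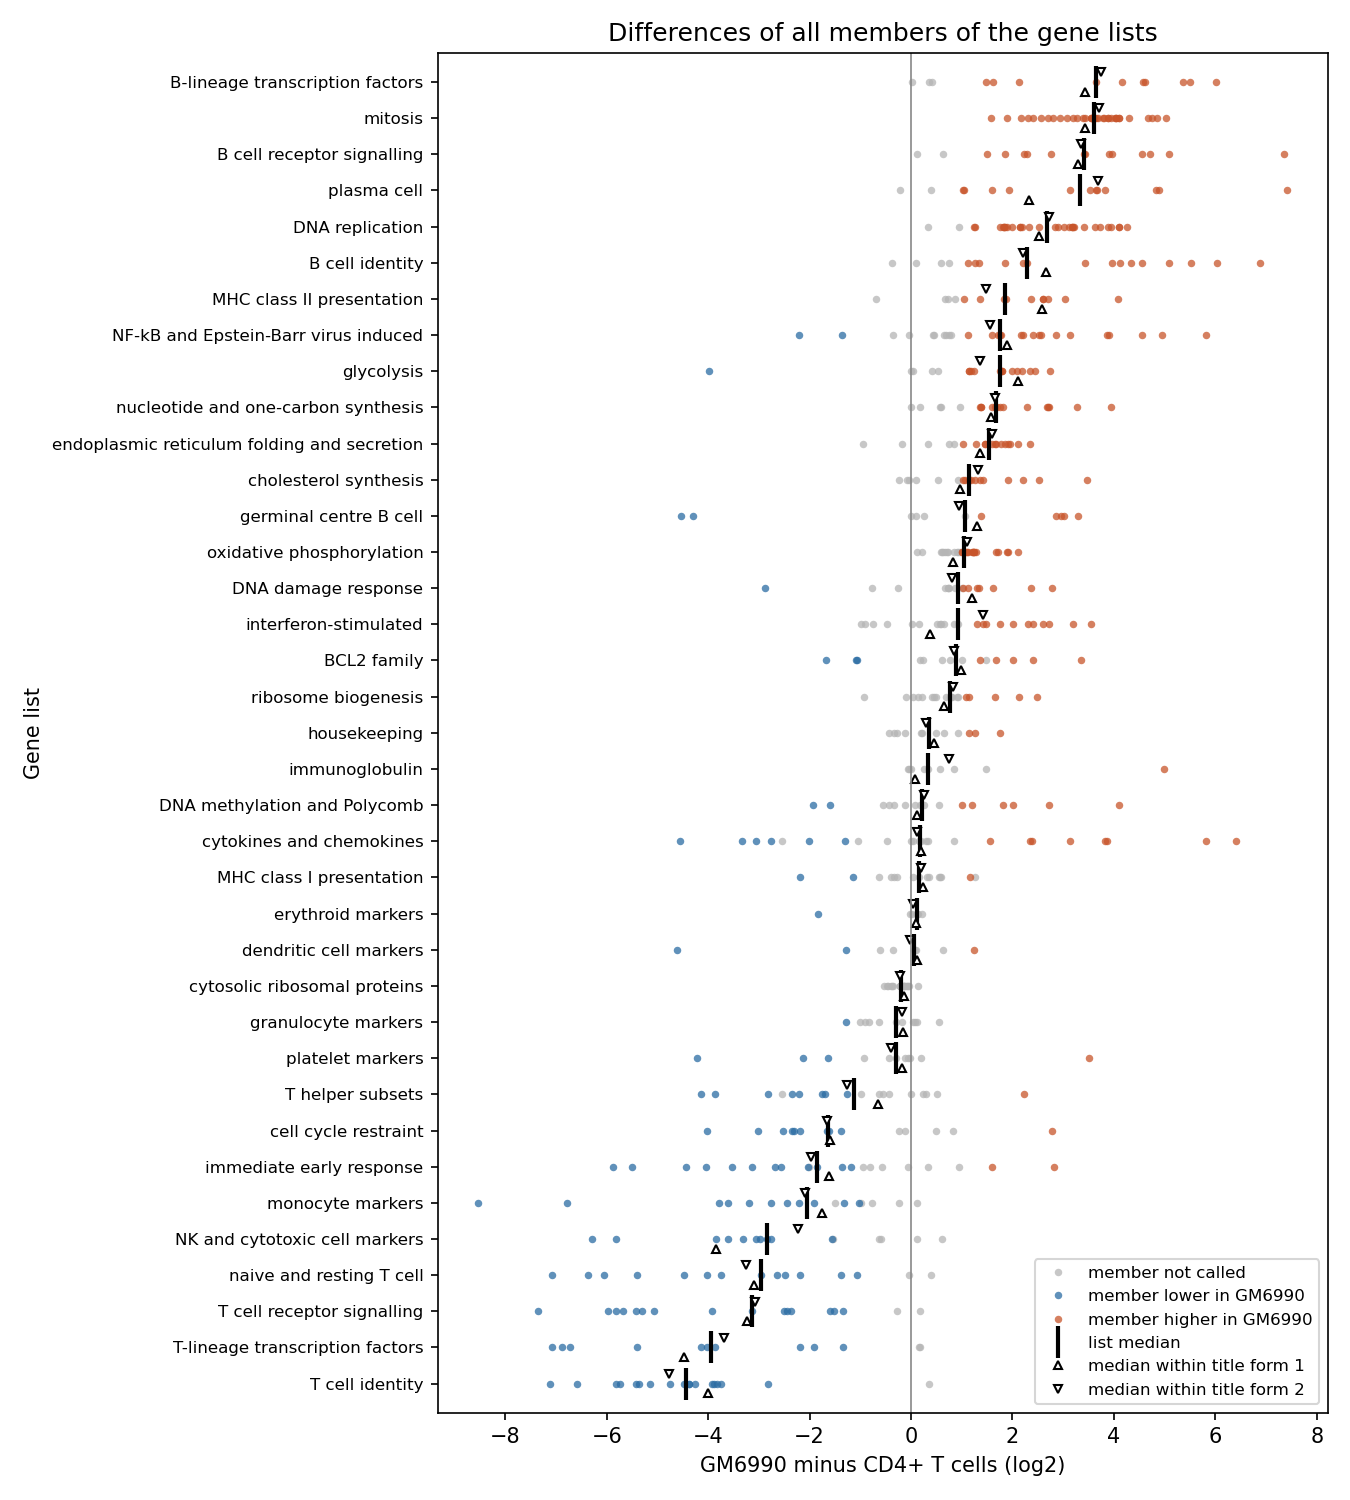
Difference GM6990 minus CD4+ T cells on the log2 scale (horizontal axis) for the measured members of the 37 gene lists (vertical axis, sorted by median), with 1 member of the nucleotide list not drawn because its level can show a genotype. Dots are genes, orange where called higher, blue where called lower and grey where not called; black bars are list medians on the deposited scale, from -4.43 for T cell identity to 3.65 for B-lineage transcription factors, and triangles are medians within each title form. Medians for T helper subsets, cell cycle restraint, cytosolic ribosomal proteins, granulocyte markers and platelet markers turned positive under poly-A centring, the last 3 of them also under hybridisation control centring.

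Across the 37 lists 27 passed the set test, 16 upward and 11 downward, and 11 did so with an estimated correlation. The lists overlap, with 596 distinct genes among 637 measured memberships.

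Arrays of different cell types correlated at 0.887 to 0.898 across probe sets within a title form and at 0.880 to 0.887 across forms. With the title form as a block, 2228 genes were higher and 1446 lower, 27 lists passed, and no list or named gene changed its call. In the 4 specimens of title form 2 alone, a setting chosen after seeing the data, 2331 were higher and 1563 lower. The differences within the forms correlated at 0.93 across genes, which are not independent replicates. Of the 3613 called genes 3027 differed by at least 1 log2 the same way in title form 1, whose specimens were also used to call them.

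The median SD over genes was 0.174 between the 3 donors and 0.156 between the 3 GM6990 samples, and 0.094 for GM6990 without its replicate 1. Repeat arrays of a specimen had a median SD of 0.083 in CD4+ T cells and 0.071 in GM6990. The values for repeat arrays and for GM6990 without replicate 1 are SDs of 2 values. Their median runs lower than that of SDs of 3 values with the same spread, so the sizes are not directly comparable. Replicate 1 of each group is also a mean of 2 arrays, and the other replicates are single arrays. The ratio of the 3' to the 5' probe sets of actin, a measure of RNA integrity, was 0.71 ± 0.16 log2 in CD4+ T cells and 0.30 ± 0.07 in GM6990 (SD, n = 3 each, two-sided exact permutation p = 0.1, the smallest that 3 against 3 allow). The same ratio for GAPDH was 0.08 ± 0.09 and -0.02 ± 0.02 (exact permutation p = 0.1).

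Spiked control transcripts read lower on the GM6990 arrays. The 24 poly-A control probe sets averaged 8.38 ± 1.34 in CD4+ T cells and 6.64 ± 1.35 in GM6990 (SD, n = 3 each, two-sided exact permutation p = 0.3), with a difference of -1.86 within title form 1 and -1.67 within title form 2. For the 18 hybridisation control probe sets the values were 10.49 ± 0.24 and 9.71 ± 0.60 (n = 3 each, exact permutation p = 0.1), with differences of -1.20 and -0.58 by title form.

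**Figure D3:**
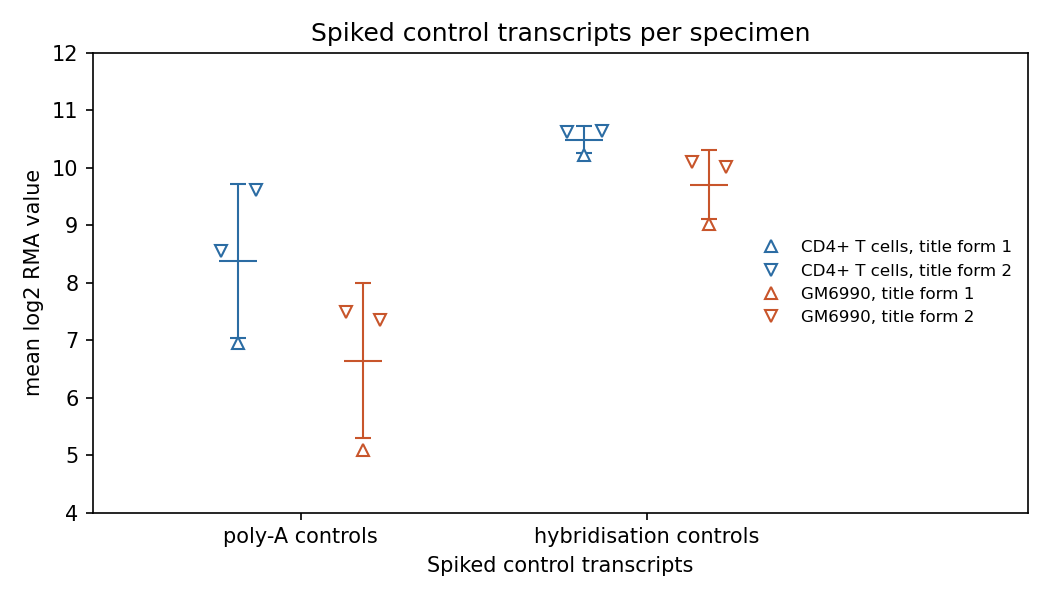
Mean log2 RMA value (vertical axis) of the poly-A and hybridisation control probe sets (horizontal axis) in each specimen of CD4+ T cells and GM6990, with the group mean and SD. The marker shape gives the title form, and within each form the GM6990 samples lie below the CD4+ T cells for both kinds of control.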

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

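The tests of the title form and of the messenger RNA share as causes of the control readings were chosen after those readings had been seen. Spiked control transcripts, which lie outside the gene comparisons, read lower on GM6990 arrays, by -1.73 log2 for the poly-A controls, meant for addition before labelling, and -0.78 for the hybridisation controls, meant for addition after it. Replicate 1 read lowest in each group for both kinds. The poly-A controls read 5.09 there in GM6990 and 6.95 in CD4+ T cells, and the hybridisation controls 9.02 and 10.22. Both groups hold the title forms in the same proportion, so a shift shared by a form cancels from the difference between the groups. The test of the title form as the whole cause therefore adds nothing to what the design fixes. Within title form 2 the poly-A controls differed by -1.67 with both GM6990 samples below both donors. A larger share of messenger RNA in GM6990 total RNA as the whole cause stays open. Before normalization it would leave the hybridisation controls alone, and these differed by -0.78 with no overlap between the groups. Array normalization can itself move these controls in samples of unlike composition, so the test could not decide. Unequal spike amounts, the effect of array normalization on samples of unlike composition and a real difference in RNA content between the cell types stay open and untested, and with them the balance of calls. Centring on the hybridisation controls left 89.6% of the calls higher in GM6990 and centring on the poly-A controls 95.9%, the latter of 888 calls. The poly-A controls also varied within the groups (SD 1.34 and 1.35, n = 3 each), so their equal addition is not given. Their difference between the groups had an exact permutation p of 0.3.

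Probe sets outside the gene comparisons, which were unnamed, had several names or belonged to genes left out by rule, also carried a signal. Of 13581 such probe sets 1581 were called, 433 higher and 1148 lower in GM6990, so 27.4% of the calls were higher, against 52.5% among the 41032 probe sets kept and 43.3% among those of them not standing for their gene.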

How the results depend on the processing

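The settings with title form 2 alone and with either control centring were chosen after seeing the data. Leaving out each specimen gave 2069 to 2263 genes higher, 1296 to 1537 lower, 5085 to 6529 past the adjusted p alone (6412 with all specimens) and 27 to 28 gene lists. The GM6990 spread then lay between 0.0937 and 0.156, the low value being without GM6990 replicate 1, as in title form 2 alone (0.0937), and the CD4 spread between 0.126 and 0.174. The low ends are SDs of 2 specimens, whose median runs lower than that of SDs of 3 with the same spread. No paired analysis was possible because no label ties a donor to a GM6990 sample, and the numbers 1 and 2 that titles share mark repeat arrays in replicate 1 and samples with separate source names in GM6990 replicates 2 and 3. Calls per probe set numbered 4047 higher, 4416 lower and 14892 past the adjusted p alone, with more features tested. The majority turned to lower only with the probe sets outside the gene comparisons, since among the 41032 within them 3614 were higher and 3268 lower. The stricter criteria gave fewer calls by construction: limma's treat against 1 log2 gave 981 and 647, and a difference of at least 2 log2 gave 698 and 540. Hybridisation control centring gave 5562 higher and 644 lower, with spreads of 0.319 (CD4) and 0.610 (GM6990). Poly-A centring gave 852 higher, 36 lower and 888 past the adjusted p alone, with spreads of 1.40 and 1.48; with spreads this wide, fewer calls passed. Centring on controls adds the same amount to the difference of every gene, so any decrease smaller than that amount must turn. Poly-A centring turned the direction of 8 named genes, none past its threshold then: HLA-E 0.66, TNFAIP3 0.45, BCL2L11 0.12, MCL1 0.73, EZH1 0.20, CLEC10A 0.51, CPA3 0.51 and PF4 0.16. Under the other settings that keep all specimens 1671 to 2743 genes were higher and 1153 to 1957 lower. A further 26 named genes lost their call with poly-A centring and 8 did with hybridisation controls. With an estimated correlation 11 lists passed, and 16 lost their call; the cause was not tested. Averaging all probe sets of a gene ended the calls of 6 named genes, CANX, BCL2L11, MCL1, EZH1, HPRT1 and CLEC4C, and taking the most variable probe set that of MCL1. Ribosomal protein centring ended those of HLA-E and MCL1. Treating GM6990 samples 2 and 3 as 1 specimen gave 2096 higher and 1294 lower and ended the call of HBB. The list of genes induced after DNA damage lost its call with the dimmest genes left out (adjusted p = 0.0555) and with ribosomal protein centring (0.0947), and the BCL2 family list gained one with either control centring (0.0231). Fry called 33 lists in 1 direction and 35 in either, and ranks 28. The random block for specimens, with a correlation of 0.748 between repeat arrays, the 8 arrays as independent, repeated quantile normalization, median centring and the title form block changed no call of the 99 named genes and 37 lists. Signal near the floor is the limit for dim genes, since without detection calls their folds are understated.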

Other observations

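The tests of covariation, of signal level and of other splits were planned, and the test for a batch marked by the title form was chosen after the resemblance of those arrays had been seen. Cytokine genes moved strongly in both directions. Of 24 measured 8 were higher and 6 lower in GM6990 (8 and 7 adjusted over the list alone), and the list missed the set test (adjusted p = 0.965, median 0.17, by title form 0.20 and 0.11). CXCL10, a chemokine induced by interferon, rose 84.9-fold and CCL22 56.4-fold. FLT3LG, a growth factor for dendritic cells, was 23.4-fold lower (adjusted p = 2.64e-05) and LTB, a lymphotoxin subunit, 10.1-fold lower (11.75 ± 0.25 to 8.42 ± 0.11, SD, n = 3 each), both calls lost with poly-A centring (adjusted p = 0.163 and 0.24). Of 14 genes of the BCL2 family, which set the threshold for apoptosis, 5 rose and 3 fell (7 and 3 adjusted over the list alone; adjusted p = 0.13, median 0.88, by title form 0.99 and 0.85). The pro-apoptotic BIK (10.2-fold) and the survival gene BCL2A1 (5.27-fold) were higher. BCL2L11, pro-apoptotic, was 3.22-fold lower and the survival gene MCL1 2.11-fold lower, and both lost their calls with hybridisation control centring (adjusted p = 0.0802 and 0.5) and turned direction under poly-A centring (0.12 and 0.73). With all probe sets of a gene averaged, 0 BCL2 family genes fell.

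Of 16 genes of DNA methylation and Polycomb 6 rose and 2 fell (6 and 2 adjusted over the list alone; adjusted p = 0.611, median 0.21, by title form 0.12 and 0.25). UHRF1, which brings the maintenance methyltransferase to replicated DNA, rose 17.2-fold (4.96 ± 0.72 to 9.06 ± 0.15, SD, n = 3 each) and the helicase HELLS 6.55-fold. CBX7, a Polycomb reader, was 3.80-fold lower, and EZH1, a Polycomb methyltransferase, 3.04-fold lower. Poly-A centring ended the call of CBX7 (-0.12, adjusted p = 0.924) and turned EZH1 (0.20), whose call was also lost with hybridisation control centring (-0.85, adjusted p = 0.0998). With all probe sets of a gene averaged, 3 rose and 1 fell. Of 16 genes induced after DNA damage 7 rose and 1 fell (8 and 1 adjusted over the list alone, median 0.93, by title form 1.20 and 0.81). CDKN1A rose 6.84-fold and the metabolic regulator TIGAR 5.13-fold, while SESN1, a stress-induced brake on growth signalling, fell 7.33-fold (adjusted p = 1.51e-04), a call lost with poly-A centring (-1.07, adjusted p = 0.402). The set test gave an adjusted p of 0.0165, lost with an estimated correlation (adjusted p = 0.463), and 4 genes rose without GM6990 replicate 1 or in title form 2 alone. MYC, a transcription factor that drives growth and was named after its values were seen, read 9.61 ± 0.19 in CD4+ T cells and 9.64 ± 0.37 in GM6990 (n = 3 each, adjusted p = 0.937).

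Most monocyte and cytotoxic cell markers were higher in the CD4+ T cell arrays, and a candidate explanation is a residue of these cells in the preparations, which negative selection should remove. The 11 called monocyte genes varied together over the 3 donors (mean pairwise correlation 0.58, percentile 99.9 of random lists of equal size and signal). The 10 called cytotoxic genes did as well (0.94, percentile 100), but so did the 12 called immediate early genes (0.47, percentile 99.6). The 17 T cell identity genes did not (percentile 16.8). With 3 donors, 1 donor could give such correlations. Replicate 1 alone has title form 1. The median shift between the forms was largest for cytotoxic markers (-0.69), so a batch could give their correlation too. It was -0.28 for immediate early and 0.13 for monocyte genes. LYZ, S100A8 and CD14 were lowest in CD4 replicate 2 and highest in replicate 3, which share a form. FOS and DUSP1 were lowest in replicate 3. For these named genes the form alone does not account for the spread, and a batch stays open for the rest. In CD4+ T cells LYZ averaged 11.52 (2.99 in GM6990), S100A8 10.08 (3.30), GZMK 9.93 (4.12) and GZMA 9.47 (3.18), levels that cannot be compared between probe sets. No monocyte marker is in another list, while CCL5 is also in the cytokine list, and at least 5 of the 15 cytotoxic markers (GZMA, GZMK, CCL5, PRF1 and NKG7) are also expressed by subsets of CD4+ T cells. Expression by the T cells themselves and a different make-up of T cell subsets between donors stay open and were not tested.

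Arrays of a title form resembled each other across the cell types. The shift of replicate 1 from the other replicates correlated across genes between CD4+ T cells and GM6990 at 0.50, which restates the resemblance that prompted the test, so a batch marked by the title form stays open. A shift depending on signal level alone is argued against, since the correlation was 0.497 after the median shift per signal level had been taken out. For title form 1230 genes passed the adjusted p, 221 of them at least 1 log2 higher and 43 lower in form 2, and 52 of these were also called between the cell types. No biological explanation for a resemblance between donors and a cell line was tested.

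The 6 specimens can be split 3 against 3 in 10 ways, too few for a share under 0.05. With the real split 3613 genes were called and 6412 passed the adjusted p alone, as in 1 of the 10 splits, and the highest number in the other splits was 0 for each. Every other split sets both cell types on each side, so their difference widens the spread within the sides. The 0 calls there are therefore no measure of chance. For gene lists the real split gave 27 and the highest other 24, in the split that set CD4 replicate 1 with GM6990 replicates 2 and 3. The other splits keep part of the difference between the cell types, so their lists do not show what chance gives either.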
